A study of Mus musculus with 6 samples.

How the data were processed

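Total RNA of the ventromedial hypothalamus was hybridised to Illumina Mouse-6 V2 BeadChips in 6 samples of Mus musculus, 3 from animals with a knockout of FoxO1 restricted to this nucleus (KO) and 3 from wild-type animals (WT). Per the series' design text, each sample is an independent pool of RNA from 3 animals, and RNA quality was checked on a Bioanalyzer; per the labels' protocols, biotin-labelled cRNA was made with an Ambion MessageAmp kit. The strain background is given as mixed. Partek is named in the submitters' processing notes, and the design text names Partek Genomics Suite 6.5. The normalization they used is not given in the sources used here.

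The deposited signal table holds probe intensity on a linear scale with a detection p-value per probe and array, per the file headers. The intensity values of the authors had already been quantile-normalized before they were deposited, although they are described as not normalized: the sorted values of the 6 arrays differ by at most 0.4, and the lowest and highest signals are 111.3 and 41187.7 on each array. They had not been background-subtracted. The authors' processed value table holds log2 values that equal the log2 of these signals within 5e-05, with no centring and no ratio taken. Its column medians are 7.30 or 7.31 on each array. Scale, centring and direction are therefore known for this table. The file headers name a detection p-value without saying what it is set against. It was taken here to set each probe against the negative controls of its array, which are not rows of the table. Totals or medians of the signal carry no information on the amount of RNA, since the normalization made them equal.

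Values were computed with limma 3.58.1 in R 4.3.3. As fixed before the data were examined, the signals went through neqc, which estimates the background from the detection p, corrects by normexp, adds an offset of 16, applies quantile normalization and takes log2. Because the signals had been normalized before, the second quantile step could change little and the background correction acted as nearly the same curve on each array. Background correction widens differences between dim probes, so fold changes depend on it. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, 20006 of 45281. Of all probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none here; of the tested probes 16825 had 1 symbol. Symbols were updated through Entrez identifiers to the RefSeq gene table of GRCm38.p6, from which no coordinates are printed because the array files name no build. That table also gave the order of genes on a chromosome and the annotated span of 99.9% of the tested genes. Probes with several symbols or none were counted and not named.

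KO and WT arrays were compared with lmFit and eBayes (2-sided, no covariates) and Benjamini-Hochberg adjustment over tested probes at 0.05; values are given as mean and SD over 3 arrays, with the SE of the difference from the model. For lists, the probe with the highest mean stood for its gene, lists with at least 3 tested genes were used, and camera was run with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it. Of 32 lists, covering hypothalamic nuclei, other brain regions, neural and non-neural cell types, FoxO targets and metabolic and signalling pathways, 30 could be tested. A probe detected on none of a group's arrays has only a bound: its group's level was set, per array, at the higher of the probe's signal and the lowest signal of a detected probe.

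Named genes follow a rule made before the data were examined: all Foxo1 probes; per direction the 12 genes with the largest fold change past the threshold whose arrays separate the genotypes, filled up by the smallest unadjusted p; for each list described, its members past the threshold or else the 2 with the smallest p; and Nr5a1, Pomc, Agrp, Npy, Bdnf, Cnr1, Lepr, Insr and Irs2. Some further genes are named outside it, after their values were seen. The lists of pancreas and other foreign tissue markers were written after pancreas transcripts had been seen.

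The test was checked on simulated data: 10 sets of 20006 probes with the means and spreads of these arrays, 200 of them changed. It recovered 0.896% of probes changed 1.5-fold, 34.6% at 2-fold and 82.9% at 4-fold, and 4.27% of all calls were false. A list shifted by 0.3 log2 was called in 10 of 10 sets, and 0 of 290 tests of other lists were positive; the simulated genes varied independently of each other, so this does not bear on correlated lists.

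Alternatives planned before the data were examined were no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' value table, no filter and a strict filter (detection p under 0.01 on 6 arrays), array weights, an intensity trend, the replicate number as a block, each array left out in turn, an unadjusted threshold, an estimated correlation and the mean of a gene's probes. Leaving out both arrays numbered 1, the mean of exocrine pancreas genes as a covariate and the removal of a trend with gene span were added after seeing the data. The arrays' number, with 4 residual degrees of freedom, limits the precision; the median SE of a difference was 0.19 log2.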

Results

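Gene expression was measured in the ventromedial hypothalamus (VMH), a cell group at the base of the brain that takes part in the control of energy balance, in mice lacking FoxO1 in this nucleus (KO) and in wild-type mice (WT). FoxO1 is a transcription factor that insulin signalling drives out of the cell nucleus. The comparison asked which transcripts of the VMH respond to the loss of FoxO1. Each genotype was represented by 3 arrays, and each array carried labelled RNA pooled from 3 animals, so that a replicate here is a pool. The array, an Illumina Mouse-6 BeadChip, reads each transcript with bead-bound probes and returned 45281 probe signals per pool. Between 18771 probes (KO 1) and 20445 probes (WT 1) were detected above background, and 20006 probes entered the tests, of which 16825 carry 1 gene symbol and stand for 10825 genes. The array files name no genome build, so no positions are given, and the precision is limited by the number of arrays. In simulated data the same test recovered 34.6% of probes changed 2-fold and 82.9% of those changed 4-fold, but 0.896% of those changed 1.5-fold. The simulation shuffled the spreads of these arrays over probes and gave each array equal noise, so recovery in the real data may differ.

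Foxo1, the targeted gene, was read by 2 tested probes that differed in direction. The brighter probe (ILMN_2656498) measured 7.01 ± 0.46 (SD, n = 3) in KO and 7.65 ± 0.18 (SD, n = 3) in WT, a difference of -0.65 log2 (SE 0.24) or 1.56-fold lower in KO. Each KO array lay below each WT array, at 6.47, 7.29 and 7.25 against 7.62, 7.49 and 7.84. The dimmer probe (ILMN_2509340) measured 5.84 ± 0.69 (SD, n = 3) in KO and 5.50 ± 0.40 (SD, n = 3) in WT, a difference of 0.34 (SE 0.35). It read near background and was detected on 2 KO arrays and 2 WT arrays. Neither difference passed the threshold of limma's moderated test with Benjamini-Hochberg adjustment (adjusted p = 0.582 for the brighter probe and 0.677 for the dimmer one). The unadjusted p of the brighter probe was 0.0265. The difference of that probe was -0.38 without KO 1 and -0.33 without background correction. That of the dimmer probe was 0.72 without KO 1, 0.050 without KO 3, 0.11 without WT 2 and 0.11 without background correction. The sources used here do not give the position of either probe relative to the deleted part of the gene, so the values do not check the genotype labels. The RNA also held Npy, a peptide of the arcuate nucleus outside the VMH, at 8.38 in WT. The share of RNA from cells with intact Foxo1 is not known.

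Across the transcriptome a single probe passed the test. It belongs to Bfar, which encodes a membrane-anchored ubiquitin ligase that restrains cell death, and it was higher in KO by 1.79 log2 (SE 0.16) or 3.47-fold. This probe (ILMN_1236693) measured 7.14 ± 0.13 (SD, n = 3) in KO and 5.35 ± 0.16 (SD, n = 3) in WT and was detected on 3 KO arrays and 1 WT array (limma adjusted p = 0.0454). The brighter Bfar probes did not share the difference: ILMN_2987995 read 0.20 higher (SE 0.16) and ILMN_2683630 0.013 higher (SE 0.14) in KO. The next smallest adjusted p, 0.311, belonged to a probe of Kptn, a subunit of a complex that restrains mTORC1 on lysosomes. That probe (ILMN_1216235) lay 1.35 log2 below WT in KO, at 5.18 ± 0.21 against 6.53 ± 0.13 (SD, n = 3 each), while the brighter Kptn probe read 0.48 higher. Bfar and Kptn were chosen after their values were seen.

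With limma, 1 probe was higher and 0 probes were lower in KO past an adjusted p of 0.05. At an unadjusted p under 0.05 there were 755 higher and 761 lower probes, 1516 in all, against 1000.3 for independent probes without any change and 180 to 1825 in the other splits of the 6 arrays into 3 against 3. All 3 KO arrays lay above all 3 WT arrays for 1769 probes and below them for 1249, together 15.1% of tested probes, where each of the 10 splits holds 10% on average. Leaving out any 1 of the 6 arrays ended the Bfar call (adjusted p from 0.130 without KO 1 to 0.371 without KO 2), with differences between 1.74 and 1.89. Without background correction the Bfar difference was 0.64 and the call was also lost (adjusted p = 0.548; 0.0156 to 0.568 over the settings tried).

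The named genes with the smallest p on the higher side did not pass the test (limma adjusted p = 0.582 for each), and their values are given without a claim of change. The beta-globin gene Hbb-b2 read 6.86 ± 0.59 in KO and 5.09 ± 0.48 in WT (SD, n = 3 each), 3.42-fold, and Alas2, the first enzyme of haem synthesis in red cells, 1.58-fold higher. Both were detected on 1 of the 3 WT arrays, and without background correction they differed by 0.61 and 0.18 log2. Itgad, an integrin subunit of white blood cells, read 2.50-fold higher (0.48 log2 without background correction; detected on 2 WT arrays), and its dimmer probe 0.99 log2 higher. Aldh1a1, a retinaldehyde dehydrogenase, read 2.14-fold higher (7.98 ± 0.46 against 6.89 ± 0.17; 0.61 log2 without background correction). Alg1 and Alg11, both mannosyltransferases that build the precursor of N-linked glycans, read 1.51-fold and 1.84-fold higher. They differed by 0.39 and 0.26 log2 without background correction, and the Alg11 probe was detected on 1 WT array, where the other Alg11 probe differed by 0.40 with overlapping arrays. Differences for Rn28s1, Rnaseh2c, H4c12, Gm266, Ifnab and Tmem160 lay between 0.65 log2 (Tmem160) and 0.94 log2 (Rn28s1), and for Tmem160 and H4c12 the other tested probe pointed the same way (0.63 and 0.80). Without background correction these 6 differed by 0.25 (Gm266) to 0.60 (Tmem160).

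On the lower side, too, the named genes did not pass (limma adjusted p = 0.582 for each). Tbx3, a transcription factor of arcuate neurons that also lie at the base of the hypothalamus, read 6.42 ± 0.27 in KO and 7.15 ± 0.29 in WT (SD, n = 3 each), a difference of -0.73, and its other probe read -0.67. Flna, which crosslinks actin filaments, differed by -0.72 and Abcc10, a membrane transporter, by -0.73. Ercc2 and Recql5, which are DNA helicases, differed by -0.61 and -0.60, and Rab3b, a GTPase of secretory vesicles, by -0.61, where its other probe differed by -0.073. Phka1, a subunit of phosphorylase kinase, differed by -0.55, Nanos2 by -0.71 and Mroh1 by -1.12, with Nanos2 detected on 2 KO arrays and Mroh1 on 1. Without background correction these 3 differed by -0.21, -0.20 and -0.34, and Tbx3, Flna, Abcc10, Ercc2, Recql5 and Rab3b by -0.19 (Recql5) to -0.37 (Flna). C030013C21Rik, Dnaaf3 and Ccdc141 were detected on no KO array and on 3 WT arrays each. For these the WT signal was at least 1.51-fold, 1.18-fold and 1.41-fold higher, measured against the lowest detected signal of each KO array or the probe's own signal, whichever was higher.

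Genes of VMH identity and of energy balance that were named in advance gave no difference past the threshold. Bdnf, a growth factor through which the VMH restrains feeding, had the smallest p among them, at 8.56 ± 0.25 in KO and 8.02 ± 0.10 in WT (SD, n = 3 each), 1.46-fold (limma adjusted p = 0.582). Each KO array lay above each WT array, and its 5 tested probes gave differences of 0.17 to 0.74. Npy, an appetite-stimulating peptide of the arcuate nucleus, read 7.90 ± 0.26 in KO and 8.38 ± 0.17 in WT, a difference of -0.48 (SE 0.18) with an adjusted p of 0.582. Nr5a1, which encodes SF-1 and marks the VMH, differed by 0.13 (SE 0.21) on its brighter probe and by -0.19 on the dimmer one. The brighter value was -0.052 without KO 2. Pomc differed by -0.059 (SE 0.33), and by 0.20, 0.077 and 0.10 without KO 2, KO 3 and WT 2. Cnr1, the cannabinoid receptor, differed by -0.034 (SE 0.19), and by 0.12 without WT 3. The insulin receptor Insr differed by -0.47 (SE 0.22) and its substrate Irs2 by -0.65 (SE 0.45), with KO 1 at 8.58 and the other KO arrays at 10.35 and 10.43. Without KO 1 the Insr difference was -0.22 and that of Irs2 -0.048, and the dimmer Insr probe differed by -0.092. Neither of the 2 Lepr probes was detected on any array, and Agrp had no named probe here.

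**Figure D1:**
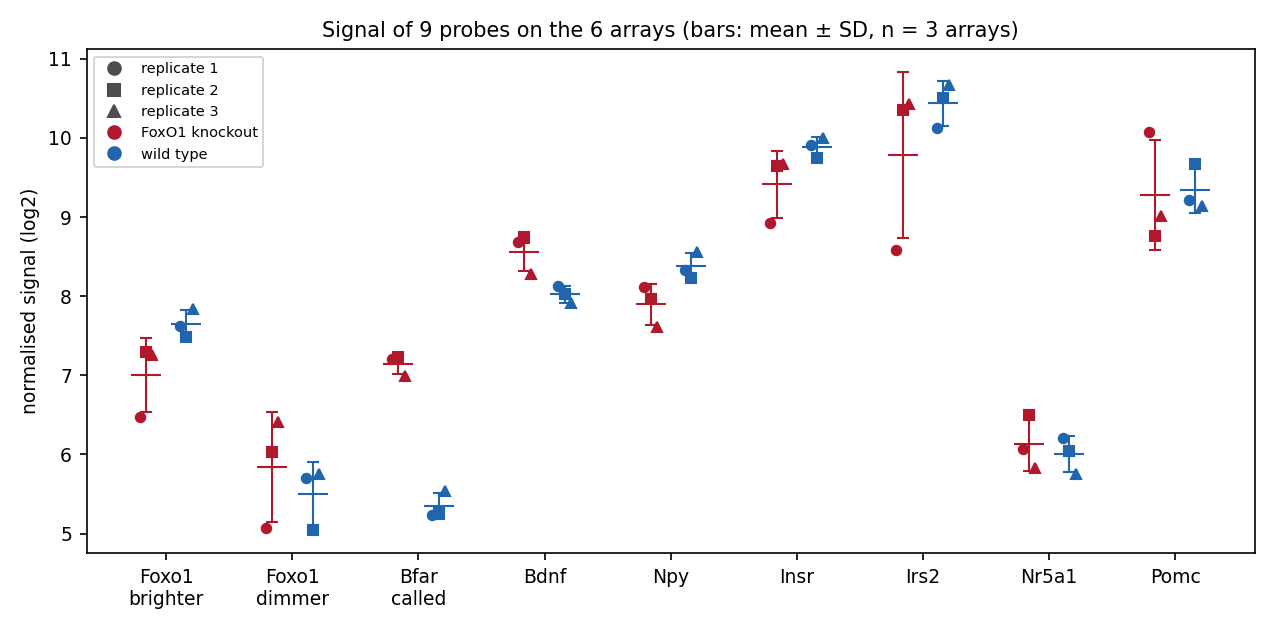
Normalised signal (log2) of 9 probes on the 6 arrays; points are arrays (red KO, blue WT; circle, square and triangle for replicates 1, 2 and 3), horizontal strokes are means and bars are SD over 3 arrays. The called Bfar probe separates KO (7.14) from WT (5.35), the Foxo1 probes differ in direction, and Irs2 is lower on KO 1 (8.58) than on the other arrays.

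Transcripts of the exocrine pancreas were detected in this hypothalamic RNA on each array, and their level differed between pools of the same genotype. The marker list used for them was written after they had been noticed. Amy2a5, which encodes pancreatic amylase, read 14.60 on a log2 scale on KO 1 and 12.43 on WT 2, and the trypsin gene Try5 read 13.29 and 9.87 on these arrays. The mean of 23 exocrine genes was 11.64 on KO 1, 10.15 on KO 2 and 8.69 on KO 3, against 11.05 on WT 1, 8.12 on WT 2 and 9.74 on WT 3. The KO mean was 10.16 ± 1.47 (SD, n = 3) and the WT mean 9.64 ± 1.47 (SD, n = 3). The difference of 0.53 lay within the spread of the pools (two-sided exact permutation p = 0.7; the smallest p that 3 against 3 allow is 0.1). KO 1 also stood apart in the whole profile, with a mean correlation of 0.954 with the other arrays, where these had 0.977 to 0.981.

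**Figure D2:**
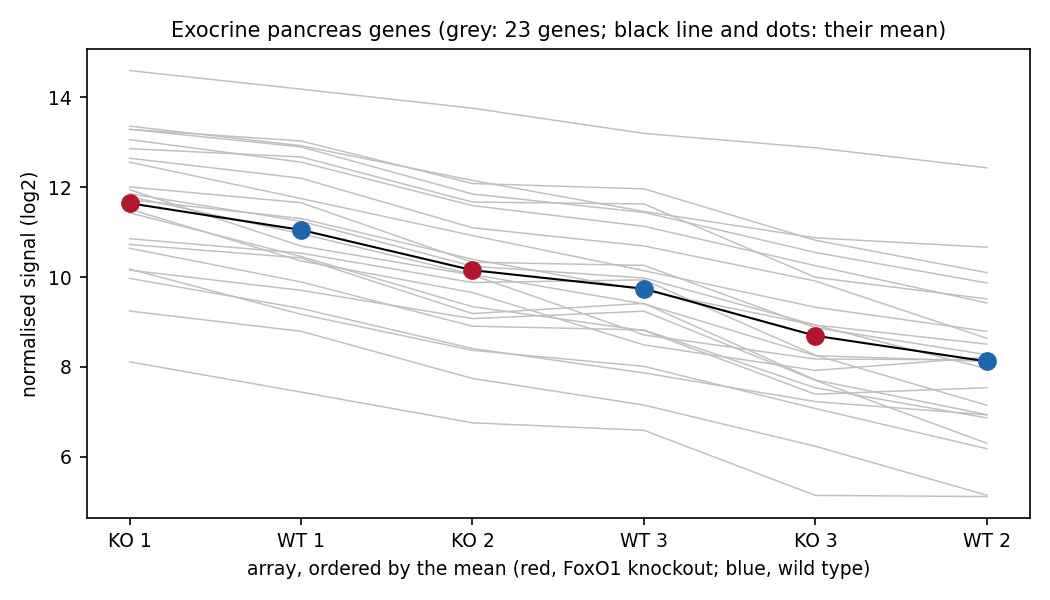
Normalised signal (log2) of 23 exocrine pancreas genes on each of the 6 arrays, which are ordered by the mean of these genes; grey lines are genes, and the black line with red (KO) and blue (WT) dots is their mean. The means run from 11.64 on KO 1 to 8.12 on WT 2, with KO and WT arrays interleaved.

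Of the 30 gene lists that were fixed in advance and could be tested, 8 passed the set test, 5 higher and 3 lower in KO (limma's camera with a preset correlation of 0.01, Benjamini-Hochberg over lists). With a correlation estimated from the arrays 0 lists passed (adjusted p = 0.689 for each of these 8). The directional rotation test fry, which asks whether the genes of a list move one way on balance, passed 0 lists after adjustment (lowest adjusted p = 0.182) and 3 at an unadjusted p under 0.05. No member of these lists passed over all genes tested. Adjusted over the list alone, 2 blood genes passed, and 0 members of the other 7 lists.

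Genes of oxidative phosphorylation, the respiratory chain and ATP synthase of mitochondria, rose as a group in KO. The median difference of 31 genes was 0.24 log2, and 29 of them were positive (camera adjusted p = 8.72e-05; adjusted p = 0.689 with an estimated correlation). Cox5b measured 14.03 ± 0.05 in KO and 13.65 ± 0.08 in WT (SD, n = 3 each), and Uqcrc1 differed by 0.35. All 16 ribosomal protein genes were positive, with a median of 0.24 (camera adjusted p = 0.0021; 0.689 is the adjusted p with an estimated correlation). Rpl35 differed by 0.37 and Rps15 by 0.38. The correlation estimated between the ribosomal genes was 0.76, so their signs are not independent counts. On KO 2 the ribosomal list had a median deviation of -0.11, below that on WT 2 (-0.039). Both groups stood highest on KO 1, the array that correlates least with the rest and is highest in pancreas transcripts, at 0.39 above the 6-array mean for each list. Without KO 1 the medians were 0.14 and 0.098. The ribosomal list lost its call with both arrays numbered 1 left out, a setting chosen after seeing the data (adjusted p = 0.0782).

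Markers of microglia, the resident macrophages of the brain, rose as a group, with a median of 0.48 over 11 genes, of which 9 were positive (camera adjusted p = 0.00437; adjusted p = 0.689 with an estimated correlation). P2ry12, a purinergic receptor of resting microglia, measured 7.01 ± 0.32 in KO and 6.33 ± 0.20 in WT (SD, n = 3 each), and Aif1 differed by 0.61. The list's deviation was 0.56 on KO 1 and 0.11 on WT 2, above the other KO arrays (0.097 and -0.023). Its median was 0.21 without KO 1, 0.29 without WT 3, 0.15 without both arrays numbered 1 and 0.27 without background correction. The list of blood markers, with 3 genes tested, rose with a median of 0.66 (camera adjusted p = 0.00123; adjusted p = 0.689 with an estimated correlation), and each KO array lay above each WT array in the list's median. That median was 0.41 without background correction. The alpha-globin gene Hba-a1, named after its values were seen, was detected on every array of both genotypes, at 12.34 ± 0.36 in KO and 11.92 ± 0.05 in WT (SD, n = 3 each).

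Chaperones and other genes of the heat shock and unfolded protein responses, called the chaperone list here, also rose as a group. Their median was 0.22 over 19 genes, 16 of them positive (camera adjusted p = 0.0106, and 0.689 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, measured 7.07 ± 0.18 in KO and 6.47 ± 0.16 in WT (SD, n = 3 each), and the cytosolic chaperone Hsp90aa1 differed by 0.41. The call was lost without KO 2 (adjusted p = 0.0606) although the median, 0.24, was no smaller. The median was 0.14 without WT 1, 0.14 without background correction and 0.10 without both arrays numbered 1.

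Genes of insulin and leptin signalling fell as a group, with a median of -0.19 over 20 genes, of which 17 were negative (camera adjusted p = 0.00336; adjusted p = 0.689 with an estimated correlation). The members with the smallest p were Tsc1, which restrains mTORC1, at 6.21 ± 0.57 in KO and 7.40 ± 0.62 in WT (SD, n = 3 each), and Igf1r, the receptor of insulin-like growth factor, with a difference of -0.79. The list was lowest on KO 1 (-0.29), and its median was -0.067 without that array. Ion channel and synaptic genes fell with a median of -0.23 over 20 genes, 16 of them negative (camera adjusted p = 0.0104; adjusted p = 0.689 with an estimated correlation). Grin2b, an NMDA receptor subunit, measured 7.99 ± 0.45 in KO and 8.94 ± 0.41 in WT (SD, n = 3 each), and Cacna1a, a presynaptic calcium channel, differed by -1.14. This list, too, was lowest on KO 1 (-0.40). Its median was -0.095 without KO 1 and -0.15 without background correction, and the call was lost without both arrays numbered 1 (adjusted p = 0.143).

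Markers of GABAergic neurons fell with a median of -0.36 over 6 genes, 5 of them negative (camera adjusted p = 0.0482; adjusted p = 0.689 with an estimated correlation). Gad2, which makes GABA, measured 11.39 ± 0.09 in KO and 11.75 ± 0.26 in WT (SD, n = 3 each), and the transcription factor Dlx1 differed by -0.36. The genotypes overlapped in the list's median deviation, with WT 1 (-0.12) below KO 2 (-0.071) and KO 3 (-0.010). The call was lost without KO 1, KO 2, WT 2 or WT 3 (adjusted p = 0.0635, 0.14, 0.0805 and 0.307; median -0.23 without WT 3), without a filter on dim probes (0.149; median -0.24) and with the pancreas mean as a covariate (0.0509; median -0.31). When a trend with gene span, the length of the annotated gene, was removed from each array, the ribosomal, chaperone and ion channel lists also lost their calls (adjusted p = 0.0866, 0.286 and 0.103; medians 0.11, 0.074 and -0.24, the last no smaller than before), and the oxidative phosphorylation median was 0.15. The covariate and the removal of the trend were chosen after seeing the data.

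**Figure D3:**
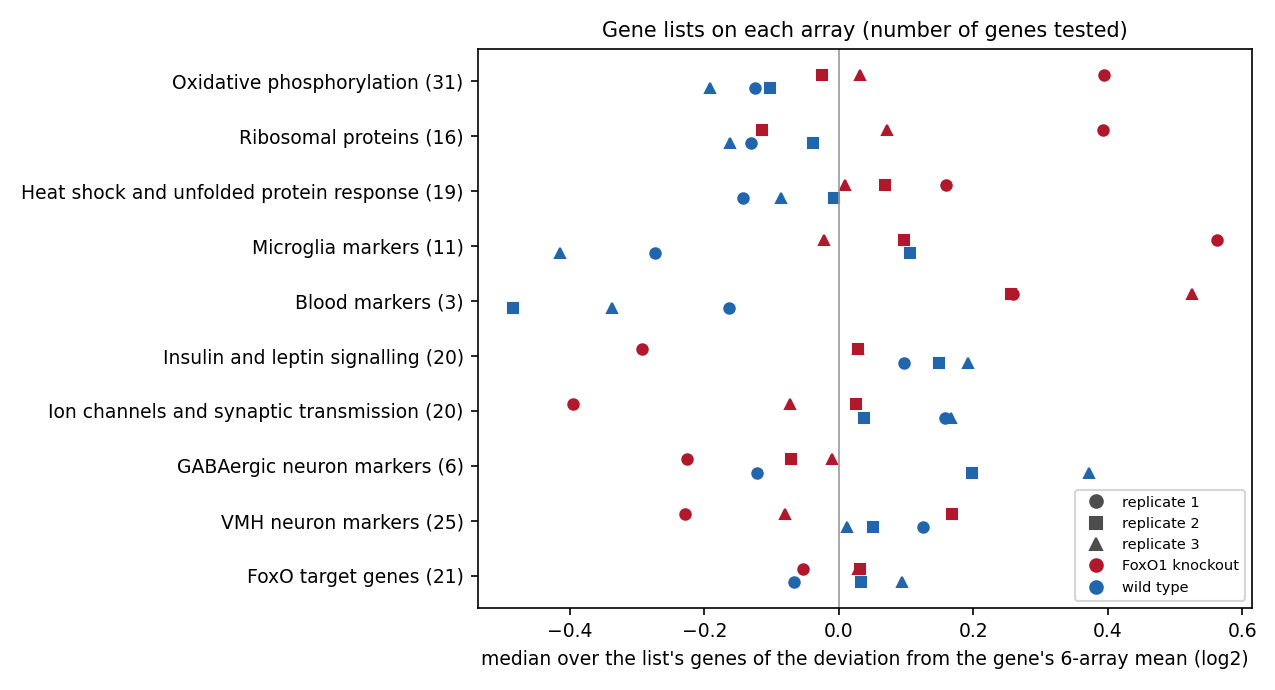
Median over each list's tested genes (number in brackets) of the deviation from the gene's mean over the 6 arrays, in log2; points are arrays (red KO, blue WT; circle, square and triangle for replicates 1, 2 and 3). The upper 8 lists passed the set test and the lower 2 did not; KO 1 lies farthest right for oxidative phosphorylation and ribosomal proteins (0.39 each) and farthest left for ion channels (-0.40).

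Lists that describe the VMH itself and the known targets of FoxO did not pass. VMH neuron markers had a median of -0.071 over 25 genes (camera adjusted p = 0.253), with Cckbr, a receptor of cholecystokinin, at 9.65 ± 0.48 in KO and 10.41 ± 0.24 in WT (SD, n = 3 each) and Bdnf on the opposite side. This list passed as lower without KO 2, with a median of -0.17 (adjusted p = 0.00955), while its median was -0.026 without KO 1 and 0.032 without both arrays numbered 1. Genes linked to control by SF-1 had a median of -0.064 over 8 genes (adjusted p = 0.95), and of 0.037 without KO 1. The 21 FoxO target genes had a median of 0.0072, a mean of -0.040 and 12 positive members, so that median and mean differed in sign (camera adjusted p = 0.884), and the median was -0.11 without WT 1. Among them Gadd45a, a stress-induced gene, differed by 0.30 and Insr by -0.47. Arcuate markers had a median of -0.20 over 11 genes (adjusted p = 0.134), with Tbx3 lower and Kiss1, which encodes kisspeptin, at 6.51 ± 0.39 in KO and 5.80 ± 0.36 in WT (SD, n = 3 each). They passed as lower without KO 1, with a median of -0.42 (adjusted p = 0.0056), and without both arrays numbered 1, with a median of -0.35 (adjusted p = 0.00888), and also with array weights (0.00954) and with the span trend removed (0.0461). Energy balance receptors had a median of -0.031 over 16 genes (adjusted p = 0.95), with the melanocortin receptor gene Mc4r 0.53 higher, and a median of 0.11 without KO 1. Astrocyte and oligodendrocyte markers had medians of 0.065 over 12 genes and 0.0081 over 11 genes, and the mean of the oligodendrocyte list was -0.0039 (adjusted p = 0.683 and 0.974). Their medians were -0.016 without KO 2 and -0.12 without KO 1. Of the FoxO family 1 gene was tested, Foxo1 itself, and of the pituitary markers 0, so these 2 lists had no set test.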

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

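Tests on pancreas RNA as a source, on genotype as its cause, on pancreas RNA in KO 1 (its second fit after the first), on detected probes in KO 1 and on span list by list were chosen after the result was seen; the limits of the islet and the other gene span tests were set once these patterns had been seen but before the tests' own values, the count of lists against span after the span correlations of the arrays, and the splits were planned.

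Of 33 quantities examined over the 6 arrays, 5 had an extreme array whose gap to its neighbour exceeded Dixon's critical ratio of 0.625, and 4 of these were lowest on KO 1. Chance marks about 1 in 20 such quantities. The mean correlation of KO 1 with the other arrays was 0.954. Insulin and leptin signalling genes had a median deviation of -0.29 on KO 1. Genes of lipid and glucose metabolism, such as the fatty acid precursor enzyme Acly and the glucose transporter Slc2a1, had a median deviation of -0.32 there. Choroid plexus markers, among them Kl and Ttr, had a median deviation of -0.30 on KO 1, but Ttr itself read 9.24 there and was lowest on KO 2, at 8.71. Markers of the lateral and dorsomedial hypothalamus, among them the peptides Nts and Nmu, were lowest on WT 1, at -0.33.

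Exocrine pancreas transcripts varied 11.5-fold between the highest and the lowest array. Genotype alone does not account for this, since WT 1 lay 2.36 log2 above KO 3 although the KO mean was the higher. Islet RNA that followed the exocrine level was not seen, but it is not excluded, as no expected islet level was computed. The hormone genes Ins2, Gcg and Pyy were detected on no array, while Iapp was detected on 4 and Ppy on 5. The 3 islet genes tested had a median rank correlation of 0.0857 with the exocrine mean. They read near the detection limit, at most 5.85, where such a correlation decides little. Exocrine RNA carried into the pools remains a candidate explanation, with 6 of the 23 genes in the top 1% of signals on KO 1 and a median pairwise rank correlation of 1 between them over the arrays. Whether it entered at dissection, extraction or labelling, and how many of these genes the hypothalamus itself expresses, was not determined.

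The low ion channel and synaptic genes of KO 1 are lower than a straight trend with pancreas RNA over the other 5 arrays predicts, with genotype as a term. KO 1 lay -0.617 log2 from the prediction, outside the 95% interval of 0.581 to each side, and -0.546 from it (0.273 to each side) with the pancreas level on a log2 scale; the fits have 2 residual degrees of freedom and reach beyond the levels of the other arrays, so the exclusion holds for such a trend only. A bias by gene span may contribute: the deviation of KO 1 had a rank correlation of -0.267 with span across genes, which are not independent replicates, but WT 1 had 0.284, so KO 1 was not the array most related to span and the test leaves this open. A lower yield also stays open, as KO 1 had the fewest detected probes but with a Dixon ratio of 0.364, under the critical value. KO 1 was also highest in muscle genes (mean 7.59). Its list medians were highest for meningeal (0.64) and for paraventricular and supraoptic markers (0.65), and lowest for cortex and amygdala markers (-0.47). These lists stayed under Dixon's critical value. Whether the tissue taken for KO 1 differed was not tested. No biological explanation was tested, since the labels put KO 1 in the same group as KO 2 and KO 3.

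A trend with gene span may underlie part of the list calls: the KO minus WT difference had a rank correlation of -0.282 with span across genes, -0.205 without KO 1 and -0.152 without both arrays numbered 1, and the highest among the other splits was 0.271 in size; GABAergic markers run against it, as their genes are about as short as those of oxidative phosphorylation (median spans of 7178.5 and 7082 bp) and fell. With the trend removed from each array, 5 of the 8 lists stayed past the set test at the preset correlation of 0.01. For 4 of them the means also lay more than 2 SE over genes from 0. These were GABAergic markers (median -0.36 before and -0.38 after), insulin and leptin signalling (-0.19 and -0.20), microglia (0.48 and 0.35) and oxidative phosphorylation (0.24 and 0.15). Both criteria take genes as nearly independent, whereas the correlations estimated from the arrays were 0.55, 0.18, 0.35 and 0.45. Span as the whole cause is therefore not excluded by them. The medians of the first 2 were no smaller after the removal, and the smaller medians of the last 2 leave a part to span open. Blood also stayed past (0.66 and 0.64), but the mean of its 3 genes, 0.77, has an SE of 0.41 and leaves span open. The calls of the other 3 ended. The chaperone list went from a mean of 0.19 (SE 0.042) to 0.071 (SE 0.040), which is what span as the whole cause predicts. Ribosomal proteins went from 0.24 (SE 0.024) to 0.11 (SE 0.024) and ion channels from -0.28 (SE 0.086) to -0.22 (SE 0.089). The medians of these 3, in this order, were 0.22 and 0.074, 0.24 and 0.11, and -0.23 and -0.24. For blood, ribosomal proteins and ion channels the set test and the mean disagreed, so span and genotype cannot be told apart. Blood stayed past the set test with a mean within 2 SE of 0. Ribosomal proteins and ion channels lost the call with means more than 2 SE from 0. A response to FoxO1 stays among the open explanations of all 8 lists, untested.

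The 6 arrays allow 10 splits into 3 against 3, too few for a share under 0.05. The real split called 1 probe and the highest other split 6, and 5 of the 10 splits called at least as many. For gene lists the real split called 8 and the highest other split 9, and 2 of the 10 called at least as many. The split with 6 probes set KO 1, KO 2 and WT 1 against the rest, which are the arrays with the highest pancreas means, and its calls were Atg3, Cd200, Lrrc59, Norad, ND5 and an unnamed probe, chosen after their values were seen. They also carry lower numbers in the deposited sample names than the other arrays, and what these numbers stand for is not given. Whether they mark a batch, which would not be balanced over genotype, was not tested, nor was anything else that these arrays share. At an unadjusted p under 0.05 the real split had 1516 probes and the other splits 180 to 1825, the highest for KO 1, KO 2 and WT 2 against the rest.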

How the results depend on the processing

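The alternatives that leave out both arrays numbered 1, add the pancreas mean or remove the span trend were chosen after seeing the data; the others were planned. The number of higher probes was 1 and became 0 with no background correction, with normexp at an offset of 50, with cyclic loess, in the authors' value table, with no filter on dim probes, with the strict filter (which does not test the Bfar probe), with an intensity trend, with the pancreas mean as covariate and with the replicate block. It stayed at 1, the Bfar probe, with median scaling, array weights and the span trend removed. Without 1 array it ranged from 0 to 1; the call without WT 1, and that with both arrays numbered 1 left out, was a probe of Glrx (3.30 and 3.10 log2 higher in KO, adjusted p = 0.0368 and 0.0113). This probe reads 10.10 on the omitted WT 1, within the range of the KO arrays, so the call rests on leaving that array out, and strain variants under the probe could not be checked without probe sequences, in a background given as mixed. The cause of these changes was not tested. The number of lower probes was 0 in every setting with an adjusted threshold. At an unadjusted p under 0.05 and a fold of at least 1.5 there were 221 higher and 489 lower probes.

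The number of lists past the set test was 8 and lay between 6 and 10 in the other settings, except 0 with an estimated correlation. Whether the replicate numbers pair the arrays was not settled. Deviations from the group means correlated at 0.146, 0.0037 and 0.402 between arrays of the same number, the highest value of each KO array. For KO 1 the value with WT 2 was close (0.104), and KO 2 correlated about equally with each WT array. The replicate block called 0 probes and 10 lists. The brighter Foxo1 probe was lower in KO in all settings, from -0.79 without KO 2 to -0.33 with no background correction, and passed in none.

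Leaving out 1 array turned the sign of 3 named genes that had no call: Nr5a1 ranged from -0.052 to 0.28, Pomc from -0.45 to 0.20 and Cnr1 from -0.19 to 0.12. Of 628 values of 34 named results under alternatives, 608 kept their sign and side of the threshold, 15 lost the call (all Bfar) and 5 changed sign. Apart from Bfar none of these results had a call to lose, so the 608 values do not speak for stable calls. Of 167 values of the 8 lists, 147 kept both and 20 lost the call. A fit with the slide as a block was not run, since the files name no slide. Signals near background limit the dim probes: Bfar differed by 1.79 log2 with background correction and by 0.64 without.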

Other observations

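The test of genes beside Foxo1 was written before its result was seen; the marker lists of foreign tissues, the search for probes with separate levels and the choice of which alternatives to print for a list came after.

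Among hypothalamic groups not described above, markers of the paraventricular and supraoptic nuclei had a median of 0.47 over 4 genes in KO, with the vasopressin gene Avp at 12.67 ± 0.71 in KO and 11.92 ± 0.27 in WT (SD, n = 3 each) and the bombesin receptor gene Brs3 0.51 higher, and did not pass (camera adjusted p = 0.0992). Their median was 0.25 without KO 1 and 0.11 without both arrays numbered 1, and they passed without WT 3 (adjusted p = 0.0379). Suprachiasmatic markers had a median of 0.30 over 5 genes (adjusted p = 0.974), with the clock gene Per2 differing by -0.83 and a median of 0.12 without KO 1, and lateral and dorsomedial markers had a median of 0.11 over 9 genes (adjusted p = 0.974), with neurotensin (Nts) 0.76 higher; the latter median turned to -0.11 without WT 1 and to -0.074 without KO 1. Markers of regions around the hypothalamus differed little: cortex and amygdala -0.013 over 7 genes, thalamus -0.15 over 8 and striatum 0.10 over 8 (adjusted p = 0.95, 0.553 and 0.95); without KO 1 the medians were 0.070, -0.019 and 0.053, and that of the striatum was -0.029 without WT 1. Meningeal and fibroblast markers had a median of 0.40 over 4 genes, with Igf2 at 10.94 ± 0.18 in KO and 10.54 ± 0.05 in WT (SD, n = 3 each) and Ogn 0.60 higher, and missed the threshold (adjusted p = 0.0528); they passed without KO 2 or WT 1 (0.0465 and 0.0126), without both arrays numbered 1 (0.0429), with cyclic loess (0.0465), the replicate block (0.0294) and the mean of a gene's probes (0.0487), and had a median of 0.15 without KO 1 (0.314). Endothelial and pericyte markers had -0.24 over 10 genes (adjusted p = 0.134), with the receptor gene Flt1 differing by -0.78 and Vwf by -0.61. They passed without KO 1 (0.0454), without both arrays numbered 1 (0.0132) and with array weights (0.00954), and had a median of -0.13 without KO 3 and -0.069 without background correction. Choroid plexus markers had -0.22 over 4 genes and tanycyte and ependymal markers 0.023 over 4 (adjusted p = 0.35 and 0.95); without WT 1 the medians were -0.11 and -0.059.

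Genes of lipid and glucose metabolism had a median of -0.16 over 17 genes and just missed the threshold (camera adjusted p = 0.0508), with Slc2a1, the main glucose transporter of the blood-brain barrier, differing by -0.33 and Acly by -0.30. Without KO 1 the median was -0.025 (adjusted p = 0.647). They passed without KO 2, KO 3, WT 1 or WT 3 (adjusted p = 0.0156, 0.0466, 0.0345 and 0.0409), with no background correction (0.0423), an offset of 50 (0.0428), cyclic loess (0.0465), the authors' value table (0.0420), the replicate block (0.0414) and the mean of a gene's probes (0.0262). Cholesterol synthesis genes had 0.091 over 12 (adjusted p = 0.586), and 0.0074 without KO 1. Immediate early genes had -0.18 over 13 (adjusted p = 0.458), with Per1 differing by -0.54 and a deviation of -0.73 on KO 1; they passed as lower without KO 3 (0.0311), but the median turned to 0.13 without KO 1 and was -0.063 without WT 3. Glucocorticoid-responsive genes had -0.020 over 13 (adjusted p = 0.95), with Nfkbia 0.46 higher and Plin4 differing by -0.56, and a median of 0.10 without WT 3. Sex-linked genes had 0.15 over 3 (adjusted p = 0.583), and -0.013 without KO 1. Of the Y-linked genes, 1 probe each of Uty and Kdm5d was detected on every array, their other probes and the 4 Xist probes on none, while an Eif2s3y probe outside the tested set read 8.97 on KO 1 and 9.13 on WT 1 and at most 4.76 on the remaining arrays. The cause of this Eif2s3y pattern, which sets both arrays numbered 1 apart from the rest, was not tested. The growth hormone gene Gh was detected on WT 1 alone, at 6.80.

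Markers of other tissues were looked at in the same way. Of 4 tested muscle genes, Myl1 read 8.44 on KO 1 and 5.30 on WT 3, and their mean was 6.81 ± 0.68 in KO and 6.25 ± 0.37 in WT (SD, n = 3 each). The mean of these genes was 7.59 on KO 1 and lay between 5.86 (WT 3) and 6.61 (WT 1) on the other arrays. The 4 tested liver genes, 1 of them Ttr, which also marks choroid plexus, had means of 6.90 ± 0.16 and 7.02 ± 0.37, and albumin (Alb) was detected on no array. The 3 islet genes had means of 5.46 ± 0.01 and 5.37 ± 0.11, the single lymphocyte gene tested, Cd3e, had 5.58 ± 0.33 and 5.62 ± 0.28, and of 6 adipose genes 0 were tested.

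Genes beside Foxo1 were examined for a difference in DNA linked to the floxed allele. Of the 40 tested genes nearest to it on its chromosome, 3 had an unadjusted p under 0.05 in limma's test, or 7.5%, against 6.36% of all 10825 genes (one-sided exact hypergeometric p = 0.472). Linked DNA and its absence cannot be told apart here, since the share lies above that of all genes but within chance for 40 genes.

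For 9 tested probes the 6 arrays fell into separate levels at least 2.5 log2 apart, with under 1 log2 within a level. These limits were set after seeing the data. The probes follow 6 different array patterns, and 0 of them separate KO from WT. Cops8 read 5.28 on KO 3 and 5.70 on WT 2 and 9.67 to 9.87 elsewhere, and Ercc5 split the arrays the same way. Sspn and Prrt4 were low on KO 1 and WT 2, Fcer1g and Lipa on KO 1, KO 3 and WT 3, Atg3 on KO 3, WT 2 and WT 3, Tomm22 on KO 2, KO 3 and WT 3, and Glrx on WT 2 (7.02) and WT 3 (6.99) against 10.09 to 10.70 elsewhere.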
